A study of Mus musculus with 39 samples.

How the data were processed

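Messenger RNA levels were measured on one-colour Agilent mouse arrays in 39 samples of right lung, with the groups taken from the sample labels (genotype, exposure and time). Per the labels, lungs were taken after exposure and snap-frozen, total RNA of whole lung was extracted with a Qiagen kit, its quality was read on a Bioanalyzer, and 500 ng was labelled with Cy3. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples. No 2 arrays held identical values (0 identical pairs).

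The deposited values are spot intensities on a linear scale. Per the file headers, the intensity of each spot was made with Agilent Feature Extraction 9.5, with spatial and multiplicative detrending and replacement values for dim spots switched on, local background correction switched off and probe positions on build mm7; the headers give no scaling between arrays. The table of the whole series held the same intensity values as the files of the single arrays, compared spot by spot, and its processing is not described in the files. Each array held 45018 spots, of which 1639 controls were left out, and the other 43379 stood for 41174 probes. Of these probes 55.7% were named by an accession number, which was replaced by a gene symbol where a table of reference sequences gave one. That table was used for names, and the coordinates are those of the array files.

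Intensities were converted to log2 and each array was scaled to its own 75th percentile, so that levels are log2 units relative to that percentile. Spots marked by the scanner software as outliers were left out. A probe entered when it was well above background on every array of at least 1 of the 12 groups, which 31340 probes were. Each gene was read from the brightest of its probes that entered, which gave 21456 genes, 15407 of them with a symbol. Between 60.3% and 80.8% of the probes on an array were well above background. Ptprz1 and Sftpc were saturated on all arrays of a group at 24 h and are not read as changes. Where 1 group of a comparison lay below background, the fold is written as "at least", computed from the mean of the brighter group over a floor, without normexp. On each array that floor was the higher of the lowest signal among probes well above background and the probe's own signal.

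A linear model with a mean for each group was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 27 residual degrees of freedom, with the package data.table, version 1.17.8). P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 21456 genes of each comparison, with a threshold of 0.05. The comparisons were ozone against air in each genotype at 24, 48 and 72 h, knockout against wild type in air (mean over the 3 times) and in ozone at each time, the interaction of genotype and ozone at each time, and the change of the ozone effect, averaged over both genotypes, from 24 to 48 h and from 48 to 72 h. The genotype difference in air was also read at each time, which was not among the comparisons fixed in advance. Standard errors are those of limma. Correlations between genotypes are across genes.

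Gene lists were tested with camera from limma, with a preset correlation between genes of 0.01 and again with an estimated one, adjusted over the lists of a comparison; a list needed 5 tested genes. The 31 lists were: MBL genes, collectins and surfactant proteins, complement and lectin pathway, acute phase and barrier response, NRF2 antioxidant genes, metallothioneins and heat shock, cytokines and chemokines, neutrophil markers, macrophage and alternative activation, type 2 and eosinophil genes, mast cell and basophil genes, T and NK cell genes, B cell genes, antigen presentation, interferon response, cell cycle and DNA replication, club cell genes, ciliated cell genes, mucous cell genes, alveolar type 1 genes, endothelial genes, fibroblast and matrix genes, glucocorticoid targets, circadian clock genes, immediate early genes, sterol and lipid synthesis, heart and skeletal muscle genes, fat tissue genes, thymus genes, red cell genes and sex genes. The lists, the comparisons, the other settings named as fixed in advance and the rule for naming genes were fixed before the data were examined. The rule named, of the genes past the threshold for which every array of 1 group lay above every array of the other, the 10 with the largest rise and the 10 with the largest fall. For the genotype difference in air this separation was asked at each of the 3 times, and for interactions and changes over time it was dropped. The rule also named the 4 members of each list past the threshold with the lowest p, and always Mbl1, Mbl2, Sftpa1 and Sftpd. Not all genes named by the rule are reported here. Genes without a symbol were counted and not named, and for an interaction or a comparison with fewer than 5 genes past the threshold the 5 genes with the lowest p were given.

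The fit was tested on simulated data with 100 genes changed by a log2 size of 1 and 100 by 2. It called 36% and 90% of them for ozone in wild type at 24 h, 53% and 93% at 48 h, 59% and 90% for the genotype difference in ozone at 48 h, and 29% and 67% for the interaction at 48 h, with 1, 3, 8 and 5 false calls.

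Other settings fixed in advance were the series table in place of the single files, normexp background correction of the raw signals with an offset of 50, quantile normalization, no filter on dim probes, the mean of all probes of a gene, slide as a fixed or as a random block, position on the slide, the replicate number as a block, arrays of the time points compared alone, an estimated correlation for the lists and leaving out each array in turn. Chosen after the data were seen were leaving out 2 libraries whose Mbl1 level goes against their label, leaving out the 6 libraries with Alb above 1 log2 unit, scores of neighbouring tissues as terms, the overall signal of the array as a term and the replicate number as a block of the 48 h air arrays alone. For 12 comparisons the arrays were also split in other ways into groups of the same sizes, with at most 100 splits drawn. The other columns of the scanner files were not used here, apart from the raw signals for normexp and the marks for background, outliers and saturation. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.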

Results

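The data were 39 one-colour microarrays of right lung from male mice aged 7 weeks, either wild type or labelled as lacking mannose-binding lectin (MBL), a soluble lectin that binds sugars on microbes and dying cells and starts complement activation. The mice breathed filtered air or ozone at 0.3 ppm without a break, with the whole body exposed, for 24, 48 or 72 h. These make 12 groups with 3 arrays in each, except for 4 arrays in each of the ozone groups at 48 and 72 h and 2 arrays in the MBL knockout air group at 72 h. The 75th percentile of the signal ran from 521 to 1316. The 24 h arrays filled 3 slides of a scan of their own and the 48 and 72 h arrays 7 slides of another, and the number of arrays limits the precision of every value.

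Mbl1 and Mbl2, the mouse genes for MBL, were read first on every array. Mbl1 (chromosome 14, 38581074 to 38583660, build mm7) was well above background on 20 of 20 wild-type arrays, at -4.85 to -1.51 log2 units relative to the 75th percentile of its array. It was well above background on 5 of the 19 arrays labelled MBL knockout, and 4 of these 5 are the 4 knockout libraries with Alb, serum albumin, above 1. In air it was lower in the knockout (adjusted p = 0.00046; 8 knockout against 9 wild-type arrays; lower in 8 of 8). As it was well above background on 2 of those 8 arrays, both at 48 h, its size is given as a bound, at least 5.28-fold at 24 h and at least 5.24-fold at 72 h. It did not pass at any single time (adjusted p = 0.16, 0.086 and 0.073) or with normexp background correction (-1.02, adjusted p = 0.11). The libraries labelled MBL knockout, ozone, 24 h, replicate 3 and MBL knockout, ozone, 48 h, replicate 1 held Mbl1 at -2.34 and -2.38, inside the wild-type range, while the other 17 lay between -8.77 and -5.51. On those 2 arrays Sftpa1, surfactant protein A, lay between 6.54 and 6.93 and Rpgrip1, a ciliary protein gene, between -3.0 and -2.34. Both lay within the range of the other knockout arrays, 6.42 to 7.34 and -3.13 to -2.25, and outside that of the wild-type arrays, 7.59 to 8.59 and -0.16 to 0.51. Mbl2 (chromosome 19, 29938699 to 29938758) was well above background on 5 of 20 wild-type and 12 of 19 knockout arrays, in air on 1 of 9 and 5 of 8, and it did not pass in air (adjusted p = 0.19). Which part of either gene the knockout removes is not given in the sources used here.

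**Figure D1:**
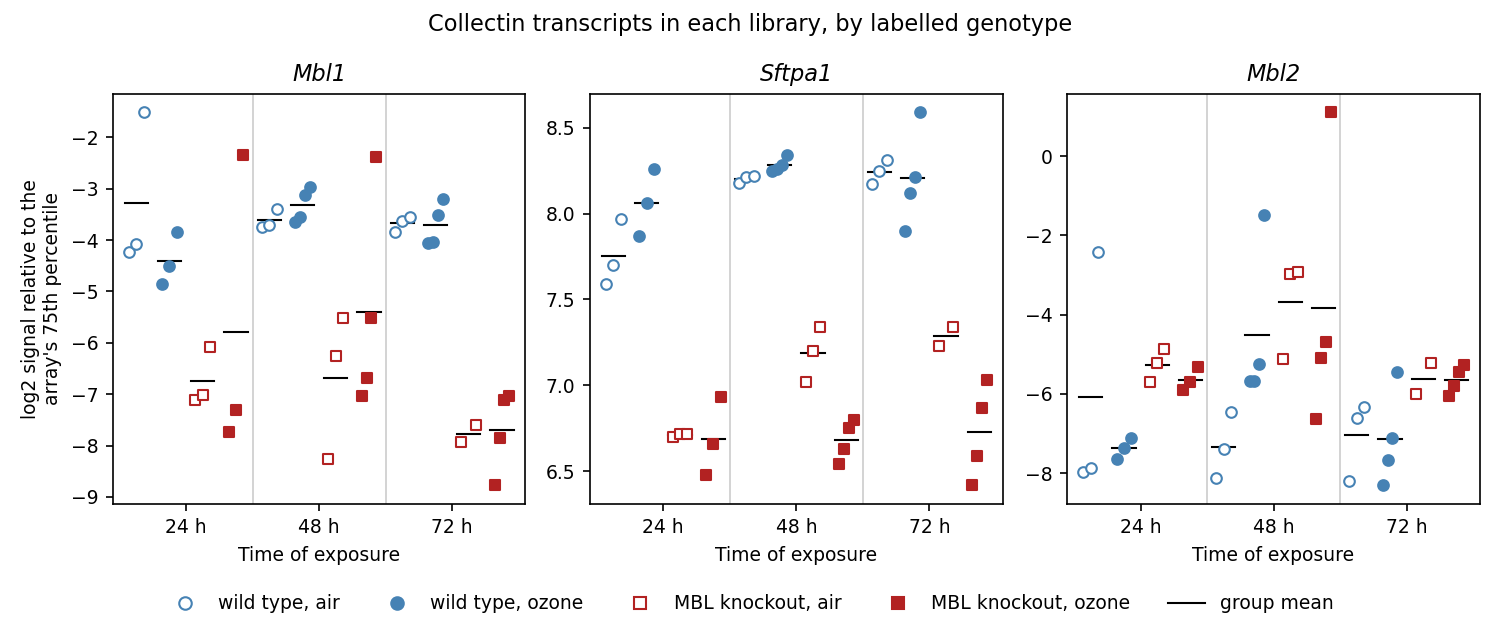
Log2 level of Mbl1, Sftpa1 and Mbl2 relative to the 75th percentile of each array (vertical axes), with one point per array and a bar at each group's mean, by genotype, exposure and time (horizontal axis). Mbl1 lay between -4.85 and -1.51 on the wild-type arrays, and 2 arrays labelled MBL knockout, at -2.34 and -2.38, lay in that range.

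The ozone comparisons within each genotype address how the lung responds to ozone over time. After 24 h, 23 of 21456 genes passed the threshold in wild-type lung, 22 of them higher (3 ozone against 3 air arrays). Sprr1a, a cross-linked envelope protein of squamous epithelium (chromosome 3, 92590070 to 92590129), rose by a log2 fold change of 2.17 ± 0.27 (standard error, SE, as throughout; adjusted p = 0.00019). Timp1, an inhibitor of matrix metalloproteinases (chromosome X, 19307699 to 19307758), rose by 2.20 ± 0.35 (adjusted p = 0.0036), and Saa2, an acute phase apolipoprotein, by 1.99 ± 0.36. Nfil3, a transcriptional repressor of the clock, rose by 1.30 ± 0.21, Dnajb1, a heat shock cochaperone, by 1.09 ± 0.22, and Pbp2 by 2.22 ± 0.38. Tshb, the beta chain of thyrotropin, rose by 2.35 ± 0.41, while another of its probes gave -0.11. Against a dim air group, Tas1r1, a taste receptor, was at least 2.62-fold higher, and Rgs8 at least 1.59-fold. Dsg1b, a desmoglein, was higher with no size given, being well above background on 1 of 3 ozone arrays. Of 10 genes named by the rule here 8 did not pass without some array. Gstt4, a glutathione transferase on chromosome 10, was the 1 lower gene, at least 2.69-fold (adjusted p = 0.041), named after its value was seen. Each gene named in the 6 ozone comparisons as past the threshold lay on the called side of the air mean on every ozone array, 3 of 3 at 24 h and 4 of 4 at 48 and 72 h.

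In wild type at 24 h, 2 of 18 genes of the acute phase and barrier list rose, and 5 did adjusted over the list alone. Their median was 0.77 (camera adjusted p = 1.6e-05, and 0.22 with an estimated correlation; both follow in this order for each list). Of the 26 genes of the NRF2 antioxidant list none passed over all genes and 2 rose adjusted over the list alone. Their median was 0.39 (camera adjusted p = 2.7e-06, and 0.36). Of 27 cytokines and chemokines 0 passed over all genes and 8 rose adjusted over the list alone. The list median was 0.40 (adjusted p = 2.9e-05, and 0.38). The 13 B cell genes had a median of -0.46, with 1 lower adjusted over the list alone (adjusted p = 1.6e-06, and 0.36). The count of 23 was 0 with the 24 h arrays fitted alone, 4 with normexp and 356 with slide as a term. With quantile normalization it was 50, with 64% of the calls higher against 95.7%. With 1 array left out it was 10 to 62, and on slide 8, the one slide with both groups, Timp1 was 3.43 higher in ozone.

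After 48 h, 888 genes passed in wild-type lung, 532 higher and 356 lower (4 ozone against 3 air arrays). Of 35 genes of the cell cycle and DNA replication list 34 rose, and 35 did adjusted over the list alone. Their median log2 fold change was 1.89 (camera adjusted p = 3.3e-85, and 2.3e-05). Uhrf1, which keeps DNA methylation through replication (chromosome 17, 54481483 to 54481542), rose by 1.89 ± 0.15 (adjusted p = 7e-09), and the mitotic kinases Aurkb and Pbk rose by 2.34 ± 0.21 and 3.44 ± 0.32. Of 18 acute phase and barrier genes 12 rose, 14 adjusted over the list alone. The list stood at a median of 2.36 (adjusted p = 3.9e-24, and 7.6e-05), and at 1.96 with tissue scores as terms. Its genes Hp, Fga, Fgb, Fgg and Itih4 are also liver genes, and the liver score was -2.21 to 0.29 on the ozone and -3.18 to -2.71 on the air arrays. Among them Saa3, an acute phase apolipoprotein (chromosome 7, 42888862 to 42888921), rose by 4.07 ± 0.52, Timp1 by 3.53 ± 0.33 and Lcn2, a siderophore-binding protein, by 2.62 ± 0.28. Of 27 cytokines and chemokines 11 rose, 14 adjusted over the list alone. The members had a median of 0.85 (adjusted p = 1.6e-18, and 0.0087). They included Ccl2, a monocyte chemoattractant (chromosome 11, 82118723 to 82118782), at 3.12 ± 0.41, and Cxcl3, a neutrophil chemoattractant, at 3.27 ± 0.47.

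Of 24 macrophage and alternative activation genes in wild type at 48 h 11 rose, 19 adjusted over the list alone. Across the list the median was 0.97 (adjusted p = 7.2e-22, and 0.0017). Mmp12, macrophage elastase (chromosome 9, 7352125 to 7352640), rose by 2.02 ± 0.26, and Retnla and Chil4, both markers of alternative activation, by 3.08 ± 0.48 and 2.35 ± 0.32. Tnc, the matrix glycoprotein tenascin C, rose by 2.59 ± 0.29, and Retnlb, a resistin-like secreted protein, was at least 14.4-fold higher. Of 20 fibroblast and matrix genes 3 rose and 1 fell, 6 and 1 adjusted over the list alone. The median was 0.32 (adjusted p = 0.00011, and 0.13). Of 15 endothelial genes 2 fell, the cadherin Cdh5 (-0.78 ± 0.18) and the claudin Cldn5 (-0.42 ± 0.12), and 6 fell adjusted over the list alone. Together they had a median of -0.31 (adjusted p = 0.0014, and 0.23). Of 16 circadian clock genes 1 rose and 3 fell, among them Dbp (-1.76 ± 0.34) and Nr1d1 (-1.30 ± 0.33), and 1 rose and 4 fell adjusted over the list alone (median -0.53, adjusted p = 0.11). Mup1, a urinary protein made in liver, rose by 6.75 ± 1.96 and Fgg, fibrinogen gamma, by 3.19 ± 0.81, in a group where Alb stood at 3.41 on replicate 4. Without that replicate Mup1 was 5.46 (adjusted p = 0.18) and Fgg 2.88 (adjusted p = 0.068). The count of 888 was 571 with normexp, which moved the median of all genes by 0.32, 464 with slide as a term and 475 without air replicate 1. With slide as a term the median was 1.92 for the cell cycle, 2.23 for the acute phase, 0.76 for the cytokine and 0.91 for the macrophage list, and on slide 7, which held 1 array of each group, 98.6% of 440 genes called without it had the same sign.

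After 72 h, 4388 genes passed in wild-type lung, 1847 higher and 2541 lower (4 ozone against 3 air arrays). All 35 cell cycle genes rose, also adjusted over the list alone (35 of 35). Their median was 2.93 (camera adjusted p = 4.7e-72, and 9e-05). Uhrf1 rose by 3.02 ± 0.15, the topoisomerase Top2a by 4.03 ± 0.24 and the cyclin Ccnb1 by 4.33 ± 0.36. Cdk1, the mitotic cyclin-dependent kinase, rose by 4.01 ± 0.36, while another of its probes gave -0.01. Of 18 acute phase and barrier genes 8 rose, 10 adjusted over the list alone, with Saa3 at 3.33 ± 0.52, Timp1 at 2.96 ± 0.33 and Lcn2 at 2.59 ± 0.28. Their median was 1.10 (adjusted p = 6.6e-08, and 0.038). Of 20 sterol and lipid synthesis genes 7 rose, and 9 rose and 1 fell adjusted over the list alone. For the list the median was 0.41 (adjusted p = 2e-05, and 0.038). Fdft1, squalene synthase, rose by 1.15 ± 0.21, and Lss, lanosterol synthase, by 1.35 ± 0.17, with 1 of its 2 other probes at 0.09. Of 27 cytokines and chemokines 14 rose and 1 fell, 15 and 1 adjusted over the list alone, with Ccl2 at 2.55 ± 0.41 and Il1rn, the interleukin 1 receptor antagonist, at 1.75 ± 0.28. The list reached a median of 0.89 (adjusted p = 7.6e-08, and 0.14).

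Of 24 macrophage genes in wild type at 72 h 12 rose, and 14 rose and 1 fell adjusted over the list alone. Members had a median of 0.81 (adjusted p = 6.2e-08, and 0.098). They included Mmp12 (2.37 ± 0.26; 0.75, adjusted p = 0.20, with normexp), Retnla (3.95 ± 0.48) and the scavenger receptor Marco (1.57 ± 0.25). Fn1, fibronectin, rose by 1.90 ± 0.28 and Krt8, an epithelial keratin, by 1.49 ± 0.22. Of 15 endothelial genes 8 fell, 8 adjusted over the list alone, with Cldn5 at -0.71 ± 0.12 and the angiopoietin receptor Tek at -0.87 ± 0.19. Over the list the median was -0.43 (adjusted p = 0.0012, and 0.21). Of 19 T and NK cell genes 8 fell, 11 adjusted over the list alone, with the NK receptor Klrb1c at -1.38 ± 0.32 and granzyme A, Gzma, at -1.52 ± 0.43. The median was -0.78 (adjusted p = 0.00075, and 0.52). Of 8 red cell genes 4 fell, 6 adjusted over the list alone (median -0.75, adjusted p = 0.0094, and 0.52), and 3 of 5 sex genes fell, 4 adjusted over the list alone. Jointly their median was -0.49 (adjusted p = 0.039, and 0.42). Igfbp3, a binding protein of insulin-like growth factors, fell by 1.84 ± 0.24, while its other probe gave -0.03, and Cyp1a1, a dioxin-induced oxygenase, fell by 1.76 ± 0.51. The count of 4388 was 1901 with normexp, 1701 with slide as a term, 2238 with the 72 h arrays alone and 2197 to 4764 with 1 array left out. With slide as a term the cell cycle median was 3.03, the acute phase 1.47 and the sterol 0.34, and no slide held arrays of both groups.

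In MBL knockout lung after 24 h, 98 genes passed, 61 higher and 37 lower (3 ozone against 3 air arrays). Of 27 cytokines and chemokines 8 rose, 11 adjusted over the list alone. Their median was 0.61 (camera adjusted p = 2.1e-17, and 0.013). Ccl2 rose by 2.91 ± 0.44 (adjusted p = 0.00088), Ccl7, another monocyte chemoattractant, by 3.00 ± 0.52 and Cxcl5, a neutrophil chemoattractant, by 4.11 ± 0.78, with 1 of 3 air arrays well above background. Il6, a cytokine that drives the acute phase (chromosome 5, 29052734 to 29052793), was at least 7.21-fold higher and Cxcl3 at least 5.86-fold. Of 18 acute phase and barrier genes 4 rose, 7 adjusted over the list alone, with Timp1 at 2.75 ± 0.35 and Saa3 at 2.63 ± 0.55. The median of the members was 0.83 (adjusted p = 1e-12, and 0.0057). Of 20 sterol and lipid synthesis genes 1 rose, Lss at 1.00 ± 0.18, and 11 did adjusted over the list alone. This list had a median of 0.48 (adjusted p = 3.9e-13, and 0.00028). Of 14 metallothionein and heat shock genes 1 rose, Dnajb1 at 0.99 ± 0.22, and 3 did adjusted over the list alone. As a list their median was 0.40 (adjusted p = 3.4e-09, and 0.040).

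Other genes that rose in the knockout at 24 h were Nfil3 (1.63 ± 0.21), the clock activator Arntl (1.13 ± 0.22), the growth factor Areg (1.52 ± 0.34) and Tnc (1.73 ± 0.31). The 10 fat tissue genes had a median of -1.35 (0 past over all genes and 0 adjusted over the list alone; adjusted p = 0.0077, and 0.61), and -0.11 with tissue scores as terms. Of the lower genes named by the rule Mrgprh was at least 4.59-fold lower. No size is given for Lrrc15, Cacna1i, Olfr763, Olfr770, Fcrl5 and Spag11a, well above background on 1 of 6 arrays, Ces4a, on 0 of 6, and Slc4a4, on 3 of 6. All 9 lay on the other side with normexp (0.06 to 0.64), which moved the median of all genes by 0.28, the other probe of Lrrc15 gave 0.28, and Lrrc15, Cacna1i and Fcrl5 without air replicate 1 and Slc4a4 without replicate 2 did not pass. The count of 98 was 29 with normexp, with 93.1% of calls higher against 62.2%. It was 163 with slide as a term, 0 with the 24 h arrays alone and 310 without the 2 libraries that went against their label on Mbl1. Leaving out 1 array gave 34 to 224, the highest without ozone replicate 3, one of those 2 libraries; with slide as a term the medians of these lists were 0.77, 0.74, 0.43 and 0.42, and on slide 10 Timp1 was 2.58 higher in ozone.

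In the knockout after 48 h, 1064 genes passed, 631 higher and 433 lower (4 ozone against 3 air arrays). All 35 cell cycle genes rose, also adjusted over the list alone (35 of 35). Their median was 2.13 (camera adjusted p = 5.9e-78, and 4.8e-05), and Uhrf1 rose by 2.65 ± 0.15 and the cyclin Ccna2 by 2.52 ± 0.22. Of 18 acute phase and barrier genes 8 rose, 9 adjusted over the list alone, with Timp1 at 3.93 ± 0.33 and Saa3 at 3.77 ± 0.52. Over all members the median was 1.12 (adjusted p = 1.8e-10, and 0.011). Of 20 sterol and lipid synthesis genes 6 rose, 11 adjusted over the list alone, including Cyp51 (1.11 ± 0.28) and Sqle, squalene epoxidase (0.52 ± 0.13). The median was 0.46 (adjusted p = 5.3e-08, and 0.0056). Of 15 endothelial genes 3 fell, Cldn5 (-0.68 ± 0.12), the endothelin receptor Ednrb (-0.84 ± 0.20) and the adhesion molecule Esam (-0.37 ± 0.11), and 12 fell adjusted over the list alone. As a group their median was -0.50 (adjusted p = 5.3e-08, and 0.022). Of 13 B cell genes 6 fell, 11 adjusted over the list alone, with the lineage factor Pax5 at -1.35 ± 0.37, though its other probe gave -0.01. Their median was -0.83 (adjusted p = 5.3e-08, and 0.17). Of 27 cytokines and chemokines 10 rose, 12 adjusted over the list alone, with Ccl2 at 2.97 ± 0.41. The list median was 0.88 (adjusted p = 5.8e-11, and 0.056). Of 24 macrophage genes 8 rose, 13 adjusted over the list alone, with Mmp12 at 1.80 ± 0.26 (1.09, adjusted p = 0.12, with normexp). The list stood at a median of 0.74 (adjusted p = 1e-08, and 0.062).

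In the same comparison Areg rose by 2.72 ± 0.31 and Tnc by 2.83 ± 0.29, and Retnlb was at least 13.5-fold higher. Cyp2f2, an oxygenase of club cells, fell by 0.70 ± 0.18 and Sftpa1 fell by 0.51 ± 0.14 (-0.80 on its other probe). Ucma, a cartilage protein, was at least 11.3-fold higher and Wfdc12, a protease inhibitor, rose by 4.00 ± 0.93, in a group where ozone replicate 1 had Alb at 5.91 and ozone replicates 1 and 2 had mean skeletal muscle scores of 5.19 and 5.09; Ucma was 3.20 (adjusted p = 0.089) with tissue scores as terms and 1.69 (adjusted p = 0.21) with normexp, which is short of the bound, and did not pass without the libraries with Alb above 1 (adjusted p = 0.16), and without ozone replicate 1 Wfdc12 was 2.22 (adjusted p = 9e-05). The 10 fat tissue genes had a median of 1.69 (0 past over all genes and 0 adjusted over the list alone; adjusted p = 0.017, and 0.60), and 0.03 with tissue scores as terms. The count of 1064 was 390 with normexp, with 76.9% of calls higher against 59.3%. It was 415 with slide as a term, 315 without the libraries with Alb above 1 and 2697 without the 2 libraries in doubt on Mbl1. Leaving out 1 array gave 522 to 2326, the highest without ozone replicate 1; with slide as a term the cell cycle, acute phase, sterol and endothelial medians were 2.08, 0.91, 0.46 and -0.45, and on slide 1, with 1 array of each group, 99.5% of 415 genes called without it had the same sign.

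In the knockout after 72 h, 782 genes passed, 575 higher and 207 lower (4 ozone against 2 air arrays). All 35 cell cycle genes rose, also adjusted over the list alone (35 of 35). Their median was 2.65 (camera adjusted p = 2.9e-98, and 6.7e-06), with Uhrf1 at 2.53 ± 0.17 and Aurkb at 3.13 ± 0.23. Of 18 acute phase and barrier genes 6 rose, 9 adjusted over the list alone, with Timp1 at 3.35 ± 0.37. The members had a median of 1.17 (adjusted p = 1e-07, and 0.045). Of 20 sterol and lipid synthesis genes 2 rose, 3 adjusted over the list alone. Across the list the median was 0.34 (adjusted p = 6.2e-05, and 0.045). Spp1, osteopontin, rose by 2.20 ± 0.32, Retnla by 3.68 ± 0.55 and Mmp12 by 1.94 ± 0.29 (1.22, adjusted p = 0.17, with normexp). Of 23 interferon response genes 4 fell, and 1 rose and 8 fell adjusted over the list alone, with the guanylate-binding protein Gbp3 at -1.25 ± 0.29 (-0.68, adjusted p = 0.41, without air replicate 1) and the antiviral Rsad2 at -1.18 ± 0.33. The median was -0.55 (adjusted p = 3.9e-06, and 0.30). Igfbp3 fell by 2.21 ± 0.28 (-0.71 on its other probe) and Cldn5 by 0.52 ± 0.14. The count of 782 was 312 with normexp, with 86.5% of calls higher against 73.5%, and 439 with slide as a term. Leaving out air replicate 1 or 2 gave 426 or 395; with slide as a term the 3 medians were 2.60, 1.33 and 0.38, and on slide 3, with 1 array of each group, 97.6% of 415 genes called without it had the same sign.

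**Figure D2:**
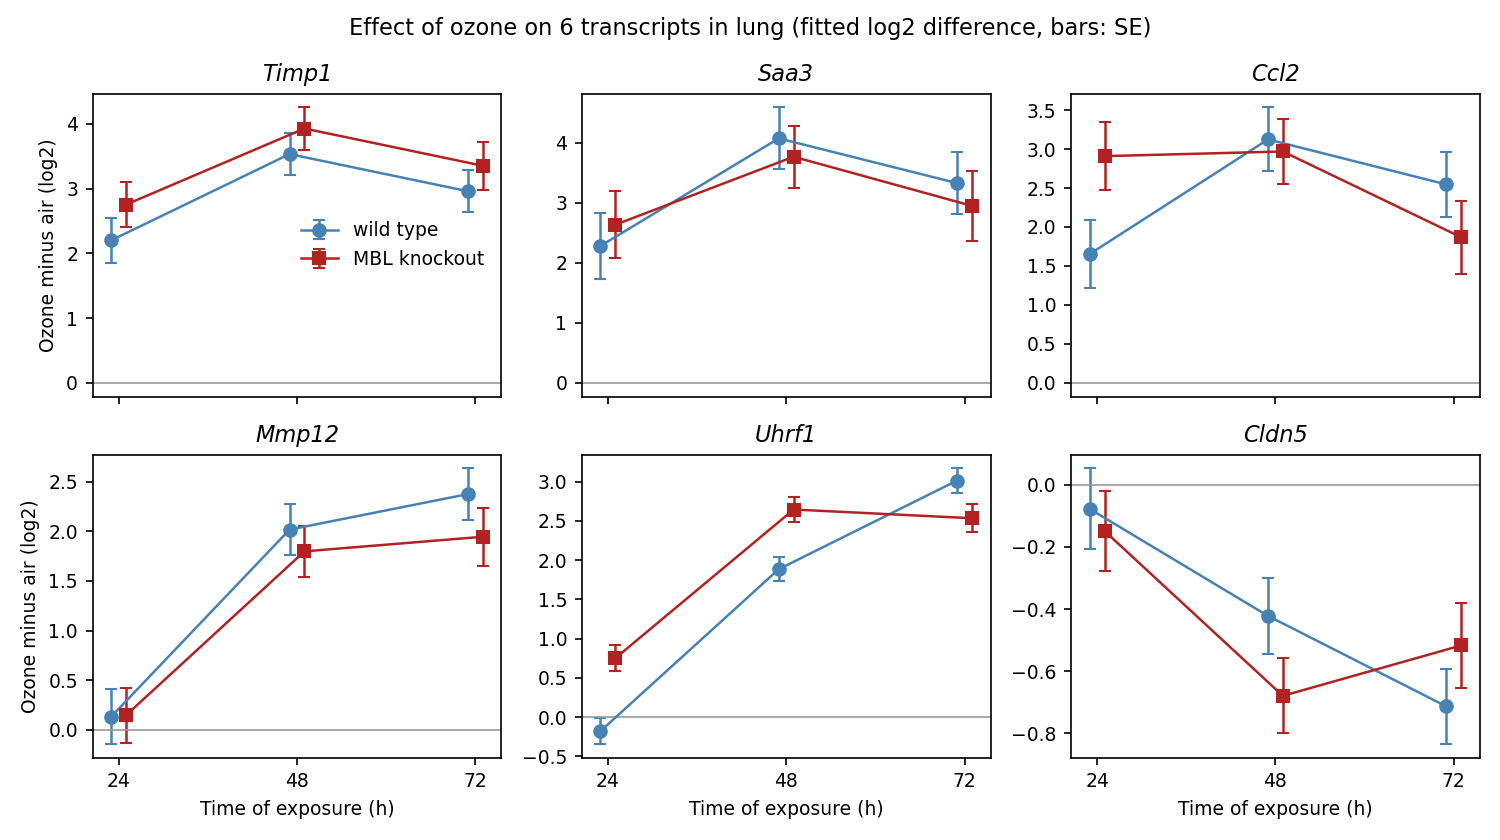
Log2 fold change of ozone against air (vertical axis, bars are 1 SE) for Timp1, Saa3, Ccl2, Mmp12, Uhrf1 and Cldn5 at 24, 48 and 72 h (horizontal axis), in wild type and MBL knockout. Timp1 was 2.20 to 3.53 in wild type and 2.75 to 3.93 in the knockout, Uhrf1 reached 3.02 and 2.65, and Cldn5 was -0.71 and -0.52 at 72 h.

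Across genes, ozone effects of the genotypes had Pearson correlations of -0.13, 0.51 and 0.68 at 24, 48 and 72 h (Spearman -0.17, 0.48 and 0.61). Genes are not independent replicates, and no array enters both effects. At 24 h slide 9 held wild-type ozone and knockout air arrays, so a slide effect enters with opposite signs and may lower that value. At 24 h 11 genes passed in both genotypes with the same sign, at 48 h 497 and at 72 h 711, against 0.1, 22.8 and 74 that random overlap would give. Across both genotypes 367 genes passed with one sign at 48 and 72 h, 315 of them higher. In the 6 ozone comparisons Mbl1, Mbl2 and Sftpd did not pass (lowest adjusted p = 0.48, 0.25 and 0.38), and Sftpa1 passed in the knockout at 48 h alone. At all times in both genotypes 6 genes passed with one sign, among them Timp1, Sprr1a, Tshb, Pbp2 and Lonrf3. The 24 h correlation was 0.15 with normexp.

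The genotype comparison in air addresses how the genotypes differ without ozone, pooled over the 3 times (8 knockout against 9 wild-type arrays). Genotype went with the place of the arrays here. At 24 h the wild-type arrays were on slide 8 and the knockout arrays on slides 9 and 10. At 48 h all wild-type arrays lay at position 1 of a slide and all knockout arrays at position 3. At 72 h they lay at 1, 2 and 2 against 4 and 3. The differences in air can thus hold differences of slide or position. Of 741 genes past the threshold 359 were higher and 382 lower in the knockout. Sftpa1 (chromosome 14, 38560683 to 38560742) was lower by -1.01 ± 0.09 (adjusted p = 1.3e-08; lower in 8 of 8 knockout arrays; -1.75 on its other probe), and Sftpd, surfactant protein D (38598705 to 38598764), by -0.86 ± 0.14; both lie beside Mbl1. Other genes lower in 8 of 8 were Rpgrip1 (-2.71 ± 0.11; chromosome 14, 47494550 to 47494608), Gdf2, a bone morphogenetic protein (at least 2.33-fold at 24 h, 5.82-fold at 48 h and 4.23-fold at 72 h; not past with normexp, adjusted p = 0.44; chromosome 14, 31378012 to 31378071), and Gcnt1, a glycosyltransferase (-4.34 ± 0.33; chromosome 19, 17027225 to 17027284). Other probes of Gcnt1 gave 0.72 and 0.78, 1 of 2 others of Rpgrip1 gave 0.02 and 1 of 2 others of Tcra 0.38. Tcra, the T cell receptor alpha chain (2.73 ± 0.18; chromosome 14, 49094000 to 49094059), the nuclease Dnase1l3 (2.07 ± 0.29) and the chromatin factor gene Supt16 (1.10 ± 0.08) were higher in 8 of 8. Mmp12 was higher by 1.16 ± 0.17 (0.41, adjusted p = 0.60, with normexp) and Chil4 by 1.10 ± 0.20 (0.55, 1.56 and 1.19 at the 3 times), and Hspa1a, an inducible heat shock protein, passed as lower with all times pooled (-1.50 ± 0.31; 7 of 8), with -1.31 at 24 h, -3.76 at 48 h and 0.58 at 72 h.

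Of 24 macrophage genes 7 were higher in the knockout in air, 14 adjusted over the list alone. Together they had a median of 0.37 (camera adjusted p = 2.8e-07, and 0.35). Of 19 T and NK cell genes 1 was higher, Ifng, and 12 were adjusted over the list alone. Their median was 0.47 (adjusted p = 2.8e-07, and 0.35). Of 16 antigen presentation genes 4 were higher, 6 adjusted over the list alone, with the class II gene H2-Aa at 0.57 ± 0.13 (7 of 8; 0.19, 0.40 and 1.10 at the 3 times). For the list the median was 0.36 (adjusted p = 2.8e-05, and 0.35). Of 15 ciliated cell genes 3 were lower, 3 adjusted over the list alone (median -0.34, adjusted p = 3.7e-05, and 0.41): the ciliary regulator Foxj1 (-0.75 ± 0.20; lower in 6 of 8), Dnah11 (-0.70 ± 0.12; 7 of 8) and Spag17 (-0.95 ± 0.21; 8 of 8). At single times these 3 passed at 48 h alone, at -1.57, -1.07 and -1.67, against -0.16, -0.13 and -0.36 at 24 h and -0.53, -0.88 and -0.82 at 72 h. Of the genes past the threshold with a position 105 of 737, or 14.2%, lay within 20 Mb of Mbl1 or Mbl2, against 3.87% of all tested genes (Fisher's exact test, p = 9.8e-32). At single times 81 genes passed at 24 h, 628 at 48 h and 197 at 72 h, with the same sign on slide 1 for 100% of 35 genes at 48 h and on slide 3 for 83.6% of 55 at 72 h. The count of 741 was 212 with normexp, 179 with slide as a term and 1166 with the replicate block. It was 324 without the libraries with Alb above 1 and 1221 without the 2 libraries in doubt on Mbl1, neither an air array. With 1 array left out it was 442 to 1076.

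**Figure D3:**
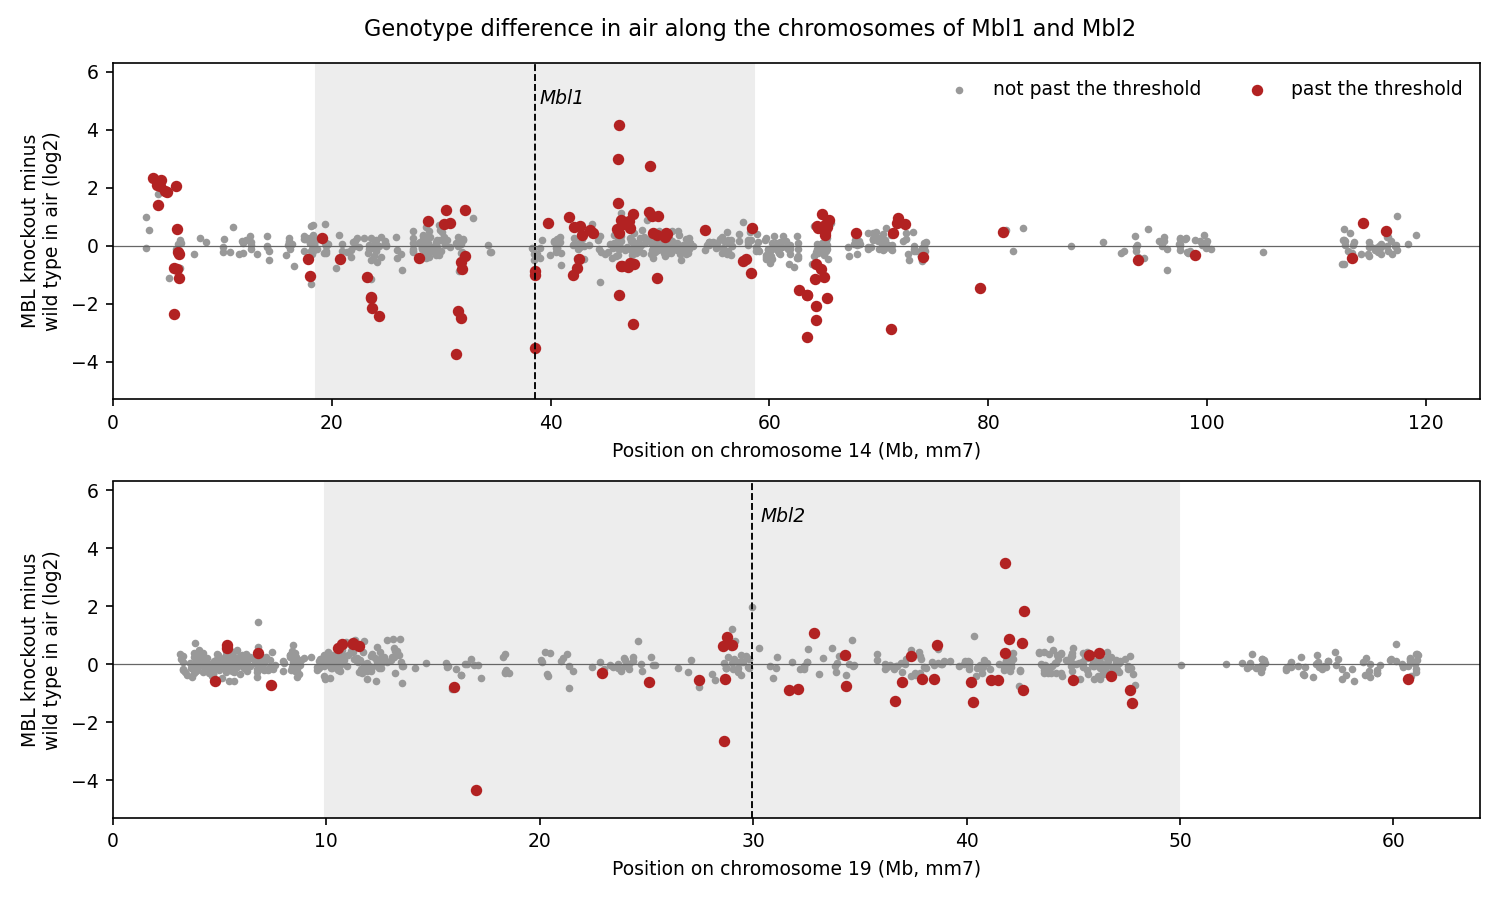
Log2 difference between MBL knockout and wild type in air (vertical axis) of the tested genes along chromosomes 14 and 19 (horizontal axis, position in Mb, build mm7), with one point per gene, red where past the threshold, and grey bands 20 Mb to each side of Mbl1 and Mbl2. On both chromosomes together 105 genes past the threshold lay inside the bands, Gcnt1 among them at -4.34.

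The genotype comparisons in ozone address how the genotypes differ under exposure, and there too genotype went with place. At 48 h wild-type arrays lay at positions 1, 1, 1 and 2 of a slide and knockout arrays at 2, 4, 3 and 3. At 72 h wild-type arrays lay at 2, 3, 2 and 2 and all knockout arrays at 4. After 24 h 36 genes passed, 16 higher and 20 lower (3 arrays against 3). Sftpa1 was lower by -1.38 ± 0.15 (adjusted p = 1.3e-06, lower in 3 of 3 knockout arrays, -2.00 on its other probe). Rpgrip1 was lower by -3.01 ± 0.18 (-0.66 on 1 of 2 other probes) and Gcnt1 by -5.12 ± 0.55 (0.67 and 0.80 on the others). Gdf2 was at least 7.52-fold lower, but with normexp its log2 difference was -0.08 (adjusted p = 0.93). Tcra was higher by 2.37 ± 0.30 and Bmp4, a bone morphogenetic protein, by 1.16 ± 0.22. Mbl1 did not pass (adjusted p = 0.91); it was well above background on 1 of 3 knockout arrays, replicate 3, with an adjusted p of 0.14 without that array and 0.027 without both libraries that went against their label. Sftpd (-0.92 ± 0.24, adjusted p = 0.14) and Mbl2 (adjusted p = 0.94) did not pass. Of 15 ciliated cell genes 0 passed, and 0 adjusted over the list alone. The list reached a median of -0.60 (adjusted p = 0.00014, and 0.42). Of 12 neutrophil markers 0 passed either way. Members had a median of 0.60 (adjusted p = 0.0036, and 0.42). Nr5a1, a steroidogenic regulator, was -2.00 ± 0.37, and 0.02 with normexp, which moved the median of all genes by 0.26. The count of 36 was 18 with normexp, 103 with quantile normalization, with 77.7% of calls higher against 44.4%. It was 77 without the 2 libraries in doubt on Mbl1, and no slide held arrays of both groups.

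After 48 h of ozone 3064 genes passed between the genotypes, 1512 higher and 1552 lower in the knockout (4 arrays against 4). Sftpa1 was lower by -1.61 ± 0.13 (lower in 4 of 4; -2.91 on its other probe), Sftpd by -0.69 ± 0.21 (-0.41, adjusted p = 0.065, without knockout replicate 1), Rpgrip1 by -2.82 ± 0.16 (-0.66 on 1 of 2 other probes) and Adamdec1, a secreted metalloproteinase (chromosome 14, 63422094 to 63422153), by -3.41 ± 0.34 (adjusted p = 2.2e-07). Mbl1, lower in 3 of 4 and well above background on 2 of 4 knockout arrays, did not pass (adjusted p = 0.088; 0.0041 without knockout replicate 1), nor did Mbl2 (adjusted p = 0.70). Of 14 metallothionein and heat shock genes 4 were lower, and 6 were lower and 1 higher adjusted over the list alone, with Hspa1a (chromosome 17, 33066911 to 33066970) at -2.93 ± 0.45. Over the list the median was -0.40 (camera adjusted p = 0.0061, and 0.48). Cdkn1a, the cell cycle inhibitor p21, was lower by -1.80 ± 0.29, and it is 1 of 6 glucocorticoid target genes of 14 that were lower, 8 adjusted over the list alone. The median was -0.68 (adjusted p = 0.00014, and 0.31). Of 26 NRF2 antioxidant genes 9 were lower, 11 adjusted over the list alone, with heme oxygenase, Hmox1, at -0.70 ± 0.14. Jointly their median was -0.30 (adjusted p = 0.00014, and 0.48). Of 18 club cell genes 9 were lower, 10 adjusted over the list alone, with Cyp2b10 at -1.16 ± 0.26. Their median was -0.56 (adjusted p = 0.00045, and 0.48). Of 15 endothelial genes 7 were lower, 8 adjusted over the list alone, with Sox17 at -0.63 ± 0.14 (-0.10 on 1 of 2 other probes). The median of the members was -0.42 (adjusted p = 5.5e-05, and 0.31).

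Higher in the same comparison were Mmp12 (0.93 ± 0.24; 0.18, adjusted p = 0.69, with normexp), the beta-glucan receptor Clec7a (1.51 ± 0.37; 3 of 4) and the epithelial cytokines Il33 (0.94 ± 0.24) and Tslp (1.21 ± 0.30). Il5ra was at least 1.58-fold higher and Il4 0.95 ± 0.31 higher (3 of 4), and with normexp, which moved the median of all genes by -0.33, they were -0.51 and -0.19. Of 16 heart and skeletal muscle genes 2 were higher, Ckm (4.64 ± 1.34) and Myl3 (4.03 ± 1.23; 0.75 on its other probe), and 2 adjusted over the list alone. This list had a median of 1.92 (adjusted p = 0.024, and 0.66). The skeletal muscle genes Myoz1 (5.19 ± 1.35) and Tnnt3 (4.93 ± 1.66) were also higher, with mean skeletal muscle scores of 5.19 and 5.09 on knockout replicates 1 and 2, and with tissue scores as terms Myoz1 was 0.61 (adjusted p = 0.14), Tnnt3 -1.05 and the list median 0.05. The 10 fat tissue genes had 1 higher, Thrsp (3.20 ± 1.03), and 1 adjusted over the list alone, with a median of 0.02 with tissue scores as terms. As a list their median was 2.51 (adjusted p = 0.020, and 0.66). The count of 3064 was 63 with slide, 112 with position on the slide and 252 with overall signal as a term. It was 1144 with normexp, with 59.4% of calls higher against 49.3% (38.4% with quantile normalization). Without the 2 libraries in doubt on Mbl1 it was 8866. Leaving out 1 array gave 463 to 8411, the highest without knockout replicate 1; on slide 5, with 1 array of each group, 88.3% of 359 genes called without it had the same sign.

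After 72 h of ozone 140 genes passed, 56 higher and 84 lower in the knockout (4 arrays against 4). Mbl1 was at least 5.03-fold lower (adjusted p = 0.018, and not past with normexp, adjusted p = 1; lower in 4 of 4), Sftpa1 lower by -1.48 ± 0.13 (-2.49 on its other probe), Rpgrip1 by -3.0 ± 0.16 (-0.17 on 1 of 2 other probes) and Adamdec1 by -3.27 ± 0.34. Tcra was higher by 1.94 ± 0.26 (0.15 on 1 of 2 others), Mmp12 by 1.25 ± 0.24 (0.85, adjusted p = 0.77, with normexp) and Bmp4 by 1.05 ± 0.19, while Sftpd (-0.65 ± 0.21, adjusted p = 0.19) and Mbl2 (adjusted p = 0.80) did not pass. Of 15 ciliated cell genes 2 were lower, Dnah11 (-0.76 ± 0.18) and Spag17 (-1.29 ± 0.30), and 4 adjusted over the list alone. Over all members the median was -0.58 (camera adjusted p = 7.2e-08, and 0.55). Of 16 antigen presentation genes 0 passed and 5 were higher adjusted over the list alone. The median was 0.39 (adjusted p = 8.4e-05, and 0.55). The count of 140 was 35 with normexp and 76 with slide as a term. It was 224 without the 2 libraries in doubt on Mbl1, neither from 72 h. With 1 array left out it was 80 to 183; the same sign was found for 78.5% of 172 genes on slide 5 and 100% of 37 on slide 6.

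Across these comparisons 23 genes differed by genotype with one sign in air and in ozone at 24, 48 and 72 h, 11 of them higher in the knockout. With known function they included Sftpa1, Rpgrip1, Gcnt1, Gdf2, Anxa8, Hps1, Tcra and Supt16, and 19 of the 23 lay within 20 Mb of Mbl1 or Mbl2.

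The interaction asks whether the ozone effect differed between the genotypes, as the knockout effect less the wild-type effect. At 24 h 3 genes passed, the itch receptor family gene Mrgprh (lower, adjusted p = 0.013; chromosome 17, 11884385 to 11884444), Tas1r1 (lower, adjusted p = 0.043; chromosome 4, 151017626 to 151017685) and the transcript AK037291 (higher, adjusted p = 0.043; chromosome 6, 145329927 to 145329986), the last named after its value was seen. Each had at least 1 group with no array well above background, so the sizes are not known, and with normexp Mrgprh was -0.66 (adjusted p = 0.71) and Tas1r1 -0.21 (adjusted p = 0.88). Of 35 cell cycle genes at 24 h 0 passed and 1 was higher adjusted over the list alone. As a group their median was 0.37 (camera adjusted p = 6.4e-06, and 0.88). At 48 and 72 h limma called 0 genes, with 657 and 630 at an unadjusted p under 0.05. The lowest p values at 48 h belonged to Igdcc4 (adjusted p = 0.71) and Gdf2 and at 72 h to Slc12a3 (adjusted p = 0.93), each with a group below background, and at 72 h also to Edn1, endothelin (1.03 ± 0.30). At 48 h 0 of 13 B cell genes passed and 4 were lower adjusted over the list alone (median -0.86, adjusted p = 7.2e-16, and 0.095), and 0 of 8 red cell genes passed and 4 were lower adjusted over the list alone. Their median was -1.05 (adjusted p = 7.7e-10, and 0.095). Of 9 mucous cell genes 0 passed, and 0 adjusted over the list alone. The list median was 0.76 (adjusted p = 0.044, and 0.53). At 72 h 0 of 16 antigen presentation genes passed, and 0 adjusted over the list alone. The list stood at a median of -0.34 (adjusted p = 0.00062, and 0.59). This list was also higher in the knockout in air at 72 h, so the same limit holds. The 24 h count of 3 was 0 with normexp, which moved the median of all genes by 0.33, 0 with position, 42 with quantile normalization, which moved it by 0.11, 213 with slide, 164 without the 2 libraries in doubt and 61 without knockout ozone replicate 3 alone; the 48 h count was 1 with tissue scores and 11 without the libraries with Alb above 1.

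The change of the ozone effect over time, averaged over both genotypes, addresses when the responses set in. From 24 to 48 h 452 genes passed, 269 with a rise and 183 with a fall. Of 35 cell cycle genes 32 rose, and 35 adjusted over the list alone, with Uhrf1 at 1.98 ± 0.16, Top2a at 2.72 ± 0.25 and Pbk at 3.55 ± 0.33. The members had a median of 2.02 (camera adjusted p = 3e-97, and 7.3e-06; 1.82 with slide as a term). Timp1 rose by 1.25 ± 0.34, Mmp12 by 1.77 ± 0.27 (0.73, adjusted p = 0.79, with normexp) and Tnc by 1.5 ± 0.30 (0.24 on 1 of 2 other probes), and Hspa1a fell by 2.56 ± 0.50 and Dnajb1 by 1.08 ± 0.21. Of 24 macrophage genes 5 rose, and 13 rose and 1 fell adjusted over the list alone. Across the list the median was 0.63 (adjusted p = 1.1e-11, and 0.056). From 48 to 72 h 16 genes passed, 15 with a rise, and the transcript ENSMUST00000023427 (-0.77 ± 0.16, adjusted p = 0.041; chromosome 16, 58439374 to 58443634), named after its value was seen, was the 1 with a fall. Of 35 cell cycle genes 3 rose, Foxm1 (1.42 ± 0.27), Tpx2 (1.32 ± 0.26) and Ube2c (1.04 ± 0.21), and 27 adjusted over the list alone. The median was 0.66 (adjusted p = 1.8e-26, and 0.045; 0.67 with slide as a term). The count of 452 was 128 with normexp, with 78.1% of calls a rise against 59.5%. It was 1249 without the 2 libraries in doubt and 799 without knockout ozone 24 h replicate 3 alone. The count of 16 was 0 with normexp, which moved the median of all genes by -0.24, 0 with slide and 1 without knockout air 48 h replicate 1.

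Lists with no call in any comparison were also measured. In wild type at 48 h the 9 collectins and surfactant proteins had 0 past over all genes and 1 lower adjusted over the list alone (median 0.10, camera adjusted p = 0.66), the 9 mast cell and basophil genes had 0 and 0 (median -0.31, adjusted p = 0.13) and the 6 thymus genes had 0 and 1 lower adjusted over the list alone (median -0.25, adjusted p = 0.51). The list of Mbl1 and Mbl2 is too short for the test, and in air Mbl1 passed as lower over all genes, while adjusted over the list alone Mbl1 was lower and Mbl2 higher. The list test and the median had opposite signs for neutrophil markers in wild type at 24 h (median 0.19, direction down) and at 72 h (median -0.14, direction up), and at neither time did 1 of the 12 pass or the test call the list (adjusted p = 0.97 and 0.76).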

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

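The tests chosen only after the result was seen were those of a donor strain segment, of loss of MBL acting anywhere in the genome, of slide and position at 48 h, and the 3 tests of the library with liver transcripts (liver tissue, a mislabelled genotype and ozone exposure).

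By the interaction test the ozone effect differed between the genotypes at 24 h for 3 genes, Mrgprh (fitted value -6.16), Tas1r1 (-3.02) and AK037291 (2.57). Each had at least 1 group with no array well above background, so these values do not give the size, and with normexp none of the 3 passed. Of the gene lists camera called 4 at 24 h, 13 at 48 h and 6 at 72 h in the interaction, and with an estimated correlation it called 0 at each time (lowest adjusted p = 0.88, 0.095 and 0.59). From 24 to 48 h the ozone effect changed for 452 genes and 7 lists, with 1 of the lists, the cell cycle, also called with an estimated correlation. Among these genes Uhrf1 (1.98), Top2a (2.72), Pbk (3.55), Timp1 (1.25), Mmp12 (1.77) and Tnc (1.5) had larger effects at 48 h, and Hspa1a (-2.56) and Dnajb1 (-1.08) smaller ones. From 48 to 72 h it changed for 16 genes and 5 lists, with the cell cycle again the 1 list called with an estimated correlation (adjusted p = 0.045). Foxm1 (1.42), Tpx2 (1.32) and Ube2c (1.04) had larger effects at 72 h and ENSMUST00000023427 (-0.77) a smaller one.

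In groups of 4 arrays, a level was singled out when its gap to the nearest other array, as a share of the range of the group, passed Dixon's 95% critical value, which chance does in about 1 in 20 tests. Of 144 tests of named genes and 24 of array measures and collectins 6 passed, no more than chance alone would give, and the 6 are listed without a reading. Mbl2 stood at -1.48 in wild type, ozone, 48 h, replicate 4, where Alb was at 3.41, with the other 3 arrays between -5.67 and -5.25. Dnajb1 stood at 4.59 on replicate 1 of that group against 5.24 to 5.29, and Il4 at -4.14 on replicate 4 against -4.60 to -4.54. In MBL knockout, ozone, 48 h, replicate 1, Ccl2 stood at 1.60 (others 2.63 to 2.71), Il4 at -4.86 (others -3.13 to -2.98) and Wfdc12 at 7.28 (others -0.48 to 0.77). Over all genes this array was the one set apart for 1625 genes, or 7.58%, and the next highest, MBL knockout, ozone, 72 h, replicate 1, for 463, or 2.16%.

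In air and in ozone at each time 23 genes differed by genotype with one sign. Of these 19 lay within 20 Mb of Mbl1 or Mbl2 (82.6% against 3.87% of all tested genes, Fisher's exact test, p = 9.3e-24). Neighbours are not independent (the probes of Rpgrip1 and Supt16 overlap), so this p and that for air are too low. The share argues against loss of MBL acting on genes anywhere in the genome as the source of the whole set. Still, LOC675467, 2610042L04Rik and Rpp14 lay outside, on chromosome 14 at 32.7 to 34.9 Mb from Mbl1. Ang3, on an unplaced sequence, was counted as outside. A candidate explanation, to which the 19 genes conform, is a segment of donor strain chromosome around the targeted genes. A probe that binds one strain's transcript less well cannot be told from a change of level. Of 6 genes with a second probe 4 had one past the threshold in the same direction, and 1 had all further probes. The choice between these counts was made after both were seen. An effect of MBL loss on neighbouring genes stays open and was not tested, and the labels name no strain.

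In ozone at 48 h 3064 genes differed by genotype, with a median size of 0.79 (median SE 0.23). Slide as a term left a median size of 0.74 (93.7%, SE 0.28, 63 genes called), and scores of neighbouring tissues left 0.75 (94.3%, SE 0.20, 5117 called). This argues against slide and against neighbouring tissue as the whole cause. Position on the slide left 0.68 (85.8%, SE 0.27, 112 called), which cannot decide, since position nearly followed genotype. The ozone arrays lay at 1, 1, 1 and 2 in wild type and 2, 4, 3 and 3 in the knockout. The air arrays at 48 h, compared below, lay at 1 and 3. With slide and position fewer genes were called as the SE rose and the sizes fell slightly. Overall signal of the array could be a cause and stays open, since it left 0.34 (42.8%; SE 0.19; 252 called), and the 75th percentile of the signal was 603 ± 104 in the knockout (SD, 4 arrays) and 799 ± 31.1 in wild type (4 arrays). A genotype difference of all animals at 48 h, in air as in ozone, also stays open, since 95.7% of 2910 called genes outside the 20 Mb windows had the same sign in air at 48 h (76.8% in ozone at 72 h and 35.7% in air at 72 h), where the signal was 666 ± 3.5 and 758 ± 110 (3 arrays each). Chance was not excluded either, since 5 of 35 splits of the 8 arrays called as many genes, with 5527 in the highest other.

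The library labelled MBL knockout, ozone, 48 h, replicate 1 held 35 of 47 liver genes at 2 log2 units or more above the mean of the other 3 arrays (74.5%; median 3.67), with Mup1 at 7.70, Serpina1d at 6.79 and Alb at 5.91. Of the 47 genes 28 were well above background on all 9 wild-type air arrays and 5 stand in another list. Ozone exposure is argued against, since 3 of the 6 libraries with Alb above 1 breathed air (wild type, 24 h, replicate 1 at 2.09 and MBL knockout, 48 h, replicates 1 and 2 at 1.19 and 2.84). Liver tissue in the sample may be the source and stays open, since 35 genes lie between the numbers set for and against it. A mislabelled genotype stays open as well, with 17 of 54 genotype markers (31.5%) nearer the wild-type mean and Mbl1 at -2.38. Gcnt1 stood at 0.51, inside the wild-type range (-0.31 to 0.83) and outside that of the other knockout arrays (-4.72 to -3.17). Mbl2 stood at 1.11, its highest level on any array. Sftpa1 and Rpgrip1, in contrast, lay in the knockout range.

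For ozone in wild type at 48 h the real split called most genes (888, 213 in the highest other of 35 splits). It did so at 72 h (4388 and 3091) and for the genotype difference in air (741 and 240, 100 drawn). These shares, 2.9% and 1%, are the lowest possible and uncorrected for the number of comparisons, so chance is not excluded. For the change from 24 to 48 h 4 of 100 splits called as many and the highest other called 9832. Those splits exchanged arrays between the scans of 24 and 48 h, so chance is undecided there. It was not excluded for ozone in the knockout at 48 h (1064 and 4908; 3 of 35 splits), the genotype difference in ozone at 72 h (140 and 2464; 2 of 35) and the interaction at 24 h (3 and 5134; 21 of 100). For the interaction at 48 h the splits decide nothing, as the real split called 0 genes (657 at an unadjusted p under 0.05 by limma) and all 100 of 100 call as many, with 6777 in the highest other. The 10 splits at 24 h are too few, with 23 genes and 4 in the highest other for ozone in wild type, 98 and 2069 for ozone in the knockout and 36 and 1461 for the genotype difference in ozone. Splits that called several times the real count, as in the knockout at 24 and 48 h, the genotype difference at 24 and 72 h, the interaction at 24 h and the change from 24 to 48 h, point to a structure of the samples other than the groups compared.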

How the results depend on the processing

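The settings tried only after the data were seen, and the tests made with them, were leaving out the 2 libraries whose Mbl1 level goes against their label, leaving out the 6 libraries with Alb above 1, tissue scores as terms, overall signal as a term and the replicate block of the 48 h air arrays alone, and for the correlations between genotypes every setting. Where a value below differs from that of the report the cause was not tested, except that leaving out arrays or fitting the arrays of some time points alone lowers the number of arrays. Signal over background and the number of arrays, 2 to 4 in a group, limit the values.

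Of 598 values of named genes, 548 kept their direction and their side of the threshold with the mean of all probes, 547 with no filter on dim probes, 549 with quantile normalization, 596 with slide as a random block (within-slide correlation -0.022), 576 with the replicate block, 441 with position on the slide, 338 with normexp and 312 with slide as a fixed block. The same held for 541 with tissue scores, 492 with overall signal, 579 without the 2 libraries in doubt and 471 without the libraries with Alb above 1. Of 5932 values with 1 array left out, 4745 kept both, 1137 kept their direction and lost the call and 8 kept it and gained one, and of 168 calls of genes named in the report 65 were lost without at least 1 array, among them 14 of 22 for ozone in the knockout at 24 h and 12 of 20 for the genotype difference in ozone at 48 h. Of 160 list calls, 152 kept both with the mean of all probes, 147 with no filter, 128 with normexp, 151 with quantile normalization, 158 with the replicate block, 160 with slide as a random block, 141 with position, 116 with slide as a fixed block, 135 with tissue scores, 131 with overall signal, 137 without the 2 libraries in doubt and 143 without the libraries with Alb above 1. With an estimated correlation 20 of the 160 list calls were made. The series table gave the same values as the single files.

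With normexp 58 of the 168 calls were lost: for ozone in wild type Dnajb1, Dsg1b, Pbp2, Rgs8, Saa2, Tas1r1 and Tshb at 24 h, Mup1 at 48 h and Mmp12 at 72 h, for ozone in the knockout Dnajb1 and the lower genes at 24 h, Cyp2f2, Esam, Mmp12, Pax5, Sftpa1, Sqle and Ucma at 48 h and Cldn5, Mmp12 and Rsad2 at 72 h, for the genotype difference Foxj1, Gdf2, H2-Aa, Ifng, Mbl1, Mmp12 and Spag17 in air, Bmp4, Gdf2 and Nr5a1 in ozone at 24 h, Il4, Il5ra, Mmp12, Myoz1, Sftpd, Thrsp, Tnnt3 and Tslp at 48 h and Dnah11, Mbl1, Mmp12 and Spag17 at 72 h, and Mrgprh and Tas1r1 (interaction), Mmp12 and Timp1 (change from 24 to 48 h) and Foxm1, Tpx2 and Ube2c (from 48 to 72 h). Of 18 "at least" bounds computed for these genes 16 were not reached with it. The counts with normexp were 4 (24 h), 571 (48 h) and 1901 (72 h) for ozone in wild type, 29, 390 and 312 for ozone in the knockout, 212 for the genotype difference in air, 18, 1144 and 35 for that in ozone, 0 for the interaction at 24 h, and 128 and 0 for the changes over time, and the 24 h correlation between genotypes was 0.15. It moved the median of all genes by -0.23 in the interaction at 48 h. With no filter on dim probes the count was 161 for ozone in the knockout at 24 h, 65 and 2012 for the genotype difference in ozone at 24 and 48 h and 6 for the interaction at 24 h, with a 24 h correlation of -0.25. With quantile normalization it was 50 for ozone in wild type at 24 h, 103 for the genotype difference in ozone at 24 h, 42 for the interaction at 24 h and 27 for the change from 48 to 72 h. It moved the median of all genes by -0.11 in the genotype difference in ozone at 48 h.

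With slide as a fixed block the counts were 356, 464 and 1701 for ozone in wild type, 163, 415 and 439 for ozone in the knockout, 179 for the genotype difference in air, 63 and 76 for that in ozone at 48 and 72 h, 213 and 1 for the interaction at 24 and 72 h, and 0 for the change from 48 to 72 h. With position on the slide they were 228 for the genotype difference in air, 62, 112 and 42 for that in ozone and 0 for the interaction at 24 h. With the replicate block the genotype difference in air gave 1166 and the interaction at 24 h 5, and the other counts stayed within 1.5 times. The replicate numbers did not pair the arrays throughout: arrays of the same number had correlations of -0.51 to 0.67. All were above 0.1 in 2 of 12 comparisons, with 0.12 to 0.43 for the 3 pairs of the genotype difference in air at 48 h and 0.55 to 0.58 for the 2 pairs of ozone in the knockout at 72 h. There the replicate block gave 890 and 760 genes against 628 and 782. As a block of the 48 h air arrays alone it gave 600 genes at 48 h and 689 with the times pooled. With the arrays of the time points alone the counts were 0 and 2238 for ozone in wild type at 24 and 72 h, 0 and 424 for ozone in the knockout at 24 and 72 h, 191 and 27 for the genotype difference in ozone at 24 and 72 h, 1 for the interaction at 24 h and 30 for the change from 48 to 72 h.

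Without the 2 libraries in doubt the counts were 36 for ozone in wild type at 24 h, 310 and 2697 for ozone in the knockout at 24 and 48 h, 1221 for the genotype difference in air, 77, 8866 and 224 for that in ozone, 164 for the interaction at 24 h, and 1249 and 46 for the changes over time, with a 24 h correlation of -0.25. Without the libraries with Alb above 1 they were 63 and 315 for ozone in the knockout at 24 and 48 h, 324 for the genotype difference in air, 4941 for that in ozone at 48 h, 1 and 11 for the interaction at 24 and 48 h, and 213 and 2 for the changes over time, with a 48 h correlation of 0.32. With tissue scores as terms they were 39 and 2725 for ozone in wild type at 24 and 48 h, 2095 and 1514 for ozone in the knockout at 48 and 72 h, 4058 for the genotype difference in air, 73, 5117 and 674 for that in ozone, 1 for the interaction at 48 h, and 1098 and 489 for the changes over time, with a 24 h correlation of -0.02. With overall signal as a term they were 2160 for ozone in wild type at 48 h, 155 and 1991 for ozone in the knockout at 24 and 72 h, 1423 for the genotype difference in air, 58, 252 and 282 for that in ozone, and 959 and 37 for the changes over time.

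Leaving out 1 array at a time, with a lone array in the knockout air group at 72 h assumed to vary like the others, gave 10 to 62 genes for ozone in wild type at 24 h (air replicates 2 and 3 left out, 11 each; ozone replicates 1, 2 and 3, 10, 51 and 62), 475 to 735 at 48 h (air replicate 1, 475) and 2197 to 4764 at 72 h (air replicates 1 and 2, 2267 and 2197; ozone replicates 3 and 4, 2858 and 2759). Ozone in the knockout gave 34 to 224 at 24 h (air replicate 2, 59; ozone replicates 1, 2 and 3, 35, 34 and 224), 522 to 2326 at 48 h (air replicates 1 and 3, 522 and 565; ozone replicate 1, 2326) and 395 to 789 at 72 h (air replicates 1 and 2, 426 and 395). The genotype difference in air gave 442 to 1076 (wild-type replicates 24 h 2, 48 h 1 and 72 h 2, 453, 456 and 483; knockout 72 h replicates 1 and 2, 442 and 470). That in ozone gave 29 to 54 at 24 h, 463 to 8411 at 48 h (wild-type replicates 1 to 4, 887, 587, 1364 and 1092; knockout replicates 1 to 4, 8411, 463, 707 and 767) and 80 to 183 at 72 h (wild-type replicate 1, 80; knockout replicates 2 and 4, 84 and 80).

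Leaving out 1 array gave 0 to 61 genes for the interaction at 24 h (wild-type air replicate 1, 1; wild-type ozone replicate 2, 8; knockout air replicates 1, 2 and 3, 7, 9 and 13; knockout ozone replicates 1, 2 and 3, 0, 0 and 61), 0 to 1 at 48 h (wild-type ozone replicate 3, 1) and 0 to 1 at 72 h (knockout air replicate 1, 1). The change from 24 to 48 h gave 325 to 799 (knockout ozone 24 h replicate 3, 799). The change from 48 to 72 h gave 1 to 39. Of the 48 h arrays left out there, wild-type air replicates 1, 2 and 3 gave 6, 4 and 25, wild-type ozone replicates 1 and 2 gave 4 and 10, knockout air replicates 1 and 3 gave 1 and 4, and knockout ozone replicates 1 and 2 gave 39 and 4. Of the 72 h arrays, wild-type air replicates 1 and 2 gave 4 and 4, wild-type ozone replicates 2, 3 and 4 gave 28, 5 and 5, knockout air replicates 1 and 2 gave 3 and 7, and knockout ozone replicates 2 and 3 gave 28 and 4.

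Directions turned for a few values. With normexp these were, for ozone in wild type, Hecw1 (0.68), Megf10 (0.60), Myh3 (0.67), Cadm2 (0.62) and Pkhd1l1 (0.51) at 48 h and Lep (-0.09) at 72 h, and for ozone in the knockout at 24 h Mrgprh (0.06), Lrrc15 (0.16), Olfr770 (0.46), Cacna1i (0.40), Fcrl5 (0.54), Olfr763 (0.57), Ces4a (0.64), Spag11a (0.61) and Slc4a4 (0.29). For the genotype difference in ozone they were Nr5a1 (0.02) at 24 h and Il5ra (-0.51), Il25 (-0.45) and Il4 (-0.19) at 48 h, and for the change from 48 to 72 h Capn6 (-0.04). The mean of all probes turned Irf1 (0.05, ozone in wild type at 72 h), no filter turned Nrxn3 (0.30 and 0.45, genotype difference in ozone at 48 and 72 h) and tissue scores turned Tnnt3 (-1.05) and Jsrp1 (-0.11) in the genotype difference in ozone at 48 h.

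Among the lists, whose direction is that of camera's test and whose value here is the median, normexp turned the NRF2 list (0.05, ozone in wild type at 48 h), the fibroblast (0.03), glucocorticoid (0.09), immediate early (0.10) and NRF2 (-0.01) lists for ozone in the knockout at 24 h and the fibroblast list (0.11) for the genotype difference in ozone at 24 h. In the interaction at 48 h it turned the alveolar type 1 (-0.15), antigen presentation (-0.11) and endothelial (-0.07) lists. Slide as a fixed block turned the red cell list for ozone in wild type (0.39) and in the interaction (-0.56) at 24 h, the glucocorticoid list for the genotype difference in ozone at 24 h (-0.02) and the interferon list in the interaction at 48 h (0.11). Tissue scores turned the fat list for ozone in the knockout at 24 h (-0.11) and 48 h (0.03), for the genotype difference in ozone at 24 h (-0.04) and 48 h (0.02) and in the interaction at 48 h (-0.22), and the heart and skeletal muscle list for the genotype difference in ozone at 48 h (0.05). Without the libraries with Alb above 1 the T and NK cell list turned in the interaction at 48 h (0.18).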

Other observations

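The tests of the genotype difference in air at single times were not among those fixed in advance, and whether the differences changed with time was not tested. In air at 48 h 628 genes differed between the genotypes (3 arrays against 3), and each gene named for that time lay on the called side of the wild-type mean on 3 of 3 knockout arrays. Of 13 B cell genes 9 were higher in the knockout, 11 adjusted over the list alone, among them Ms4a1, the surface antigen CD20 (2.01 ± 0.44), the low-affinity IgE receptor Fcer2a (1.57 ± 0.33) and Cd79b, a chain of the B cell receptor (1.58 ± 0.33). Taken as a list they had a median of 1.37 (camera adjusted p = 3.8e-12, and adjusted p = 0.27 with an estimated correlation). Of 14 metallothionein and heat shock genes 5 were lower, 5 adjusted over the list alone, with Hspa1a at -3.76 ± 0.51, the cochaperone Dnajb1 at -1.39 ± 0.22 and Hsph1 at -1.71 ± 0.31 (median -0.47, adjusted p = 6.2e-05, and adjusted p = 0.29 with an estimated correlation). Of 16 circadian clock genes 2 were lower, the period genes Per2 (-1.61 ± 0.32) and Per1 (-1.38 ± 0.38; adjusted p = 0.043, and 0.052 with the replicate block of these arrays alone), and 5 adjusted over the list alone (median -0.44, adjusted p = 0.00063, and adjusted p = 0.29 with an estimated correlation). Mup1 was higher by 9.80 ± 2.10, in a group whose replicates 1 and 2 had Alb at 1.19 and 2.84.

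In air at 72 h 197 genes differed (2 knockout against 3 wild-type arrays), with each named gene on the called side on 2 of 2 knockout arrays. Of 16 antigen presentation genes 2 were higher, the class II genes H2-Aa (1.10 ± 0.24) and H2-DMa (1.14 ± 0.28), and 9 adjusted over the list alone (median 0.75, camera adjusted p = 2.3e-09, and adjusted p = 0.23 with an estimated correlation). Of 23 interferon response genes 1 was higher, the transcription factor Irf7 (1.33 ± 0.33), and 2 adjusted over the list alone (median 0.52, adjusted p = 2.3e-09, and adjusted p = 0.49 with an estimated correlation). After 72 h of ozone in wild type 6 of 22 complement and lectin pathway genes rose and 1 fell, also adjusted over the list alone, with C1qa at 0.95 ± 0.22, factor B, Cfb, at 0.68 ± 0.16 and clusterin, Clu, at 1.62 ± 0.23 (median 0.35, adjusted p = 0.0074, and adjusted p = 0.38 with an estimated correlation). In the knockout at 48 h 2 of 13 type 2 and eosinophil genes rose, 3 adjusted over the list alone (median 0.33, adjusted p = 0.038, and adjusted p = 0.38 with an estimated correlation). There 1 of 12 alveolar type 1 genes rose and 2 fell, 1 and 4 adjusted over the list alone (median -0.33, adjusted p = 0.028, and adjusted p = 0.35 with an estimated correlation). In air, pooled over the times, 2 of 15 immediate early genes were lower in the knockout, 3 adjusted over the list alone (median -0.17, adjusted p = 0.010, and adjusted p = 0.51 with an estimated correlation).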
